A study of Sus scrofa with 23 samples.

How the data were processed

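RNA was measured in the prefrontal cortex of 23 female adolescent pigs of 20 kg by poly-A selected RNA sequencing (NEBNext Ultra 2). Each animal gave 1 library. Awake animals had received 1 intravenous injection of saline or of 0.08 mg/kg psilocybin, and were killed by pentobarbital 1 day or 1 week later. The brain was snap frozen.

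The deposited table holds expected counts for 25880 Ensembl genes, made by the authors with featureCounts, which can split a read between overlapping genes. Per the submitters' processing notes, reads were trimmed with fastp 0.20.0, aligned with STAR 2.6c to the pig genome build susScr11 and counted with featureCounts 1.5.1. Per the file headers, only primary alignments and read pairs with both ends mapped were counted, reads overlapping several genes were given to each in fractions, and counting ignored the strand. Of all values 72.2% were whole at a tolerance of 0. The others are the fractions that shared reads give. Values were rounded to whole counts for the count models, which changed the total of any library by at most 0.001%. Counting without strand adds reads of an overlapping gene on the opposite strand, and sharing reads in fractions adds part of those of overlapping genes on the same strand. Of 74 genes named by the rule given below, 24 overlap another annotated gene, 12 of them on the same strand and 15 on the other. Near-identical copies in the GBP, IFIT, SLA and ribosomal protein families make the counts of their members uncertain. Symbols were found for 14857 of the 25880 identifiers. A genome sequence and an annotation of the build were not used here, and gene positions are the span of the exons listed in the table, on susScr11.

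The animals form 4 groups by treatment and time, and the labels divide them into 2 batches of 11 and 12 libraries that are crossed with the groups. Animal numbers are not shared between groups (0 shared), so no pairing was used. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 15049, of which 12495 have a symbol. Libraries were scaled by TMM. Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust dispersion and robust fit) in R 4.3.3, in 1 model with a term for each of the 4 groups and a term for batch. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed. The 6 comparisons were psilocybin against saline at 1 day and at 1 week, the difference between those effects, their average, and 1 week against 1 day within saline and within psilocybin. All tests were two-sided. Fold changes are on the log2 scale with their standard error (SE) or 95% confidence interval, and levels are in CPM (each count scaled by its library's TMM-adjusted total, as edgeR's cpm function gives it) with the standard deviation (SD) between animals.

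Before the data were examined, 33 gene lists for the tissue and the treatment, 12 genes of interest and the rule for naming genes were fixed. The 31 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 31 lists. Camera with a correlation estimated from the data and fry, which tests whether a list's genes move one way on balance, were alternatives. List scores are the mean over members of log2 CPM (prior count 2), each relative to its mean over the 23 libraries. After the data were seen, list scores were also compared by an exact permutation of the treatment labels within each time and batch, which has 200 arrangements at 1 day, 400 at 1 week and 80000 for the difference. At 1 day and at 1 week these are too few for 1 list on its own to pass after adjustment over 31 lists. The naming rule takes, in each comparison of psilocybin with saline, up to 10 genes with the smallest p per direction among those past the threshold. If fewer than 10 pass, the genes next by p are named until 10 are reached and are given as values that did not pass. The rule adds the 12 genes fixed in advance and the 4 members with the smallest p of every list that passed. In the other comparisons it names only genes past the threshold.

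The alternatives were RLE size factors, no filter, a stricter filter (1 CPM in at least 5 libraries), DESeq2 1.42.0, limma-voom, a non-robust fit, no batch term, the compared groups alone, each batch alone, 1 surrogate variable from sva 3.50.0, and leaving out each animal in turn. For the mitochondrially encoded share, the 10 most abundant nuclear genes were left out of the denominator. The removal of 3 libraries standing apart was added after the data were seen, as were all alternatives for the batches and for the lists of the time comparisons. The models were tested on simulated counts and on thinned real libraries. With changes set into the thinned libraries, 2-fold changes were recovered for 79.7% of 69 genes at 1 day and 85.5% of 69 at 1 week, and 1.5-fold changes for 53.7% of 67 and 61.8% of 68. These were set in together with 3-fold changes of 64 genes at 1 day and 63 at 1 week. Many changed genes ease the adjusted threshold, so the shares do not hold for a lone changed gene, which is harder to find. Among 14834 genes without a set change, 3 were called at 1 day and 0 at 1 week, where edgeR gave 421 and 298 with an unadjusted p under 0.05; DESeq2 and limma were not run on them. Library totals lay between 9504421 and 18654626 counts. Polymerase chain reaction copies are not independent molecules, and the precision of each comparison was taken from the spread between animals. Behaviour and receptor occupancy, which the series title also names, are not in the deposited table and were not analysed here.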

Results

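Gene expression was measured in the prefrontal cortex of pigs 1 day or 1 week after 1 dose of psilocybin, a tryptamine whose metabolite psilocin activates the 5-HT2A receptor, or after saline. The groups held 6 animals 1 day after psilocybin, 5 animals 1 day after saline, and 6 animals each 1 week after psilocybin and after saline. The series states 6 animals in every group, so 1 saline animal of the 1 day groups is not in the table. Each group of 6 had 3 animals in each batch, and the saline 1 day group had 2 in batch 1 and 3 in batch 2. Assigned counts per library ranged from 9975409 to 18654626 1 day after psilocybin, from 11453787 to 17206665 1 day after saline, from 9504421 to 13567768 1 week after psilocybin and from 10570456 to 16212439 1 week after saline. Animals are numbered within each group in the order of the submitters' animal numbers. Mitochondrially encoded genes took 11.49% ± 2.76 (SD, n = 6) of counts 1 day after psilocybin and 11.67% ± 3.10 (SD, n = 5) after saline. At 1 week they took 12.28% ± 1.70 and 12.82% ± 1.43 (SD, n = 6 each). The difference between treatments in this share did not pass at 1 day (-0.303 percentage points, 0.963 in batch 1 and -1.57 in batch 2, exact permutation p = 0.855) or at 1 week (-0.54 points, -0.793 and -0.287 within the batches, exact permutation p = 0.455). After the batch term was removed, the first principal component held 21.3% of the variance. Saline 1 day animal 5 (40.06), saline 1 week animal 1 (37.75) and psilocybin 1 week animal 6 (28.34) had the highest scores on it. These 3 libraries also had high mean log2 scores of ribosomal protein genes (0.87, 0.66 and 0.38) and of nuclear respiratory chain genes (0.56, 0.47 and 0.30), relative to the mean over all libraries.

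The first comparison addressed which genes differ in the cortex 1 day after psilocybin. No single gene passed: 0 of 15049 passed with edgeR. Across gene lists, 33 of 37 interferon response genes were lower 1 day after psilocybin (median log2 fold change -0.29). Nuclear genes of the mitochondrial respiratory chain (52 of 56 lower, median -0.20) and cytosolic ribosomal protein genes (44 of 45 lower, median -0.23) were also lower, and astrocyte markers were higher (13 of 15, median 0.15). These lists passed camera with a preset correlation but not with an estimated one. Without saline animal 5 the mean log2 fold change was 0.002 in place of -0.194 for the respiratory chain genes. For the ribosomal protein genes it was then 0.098 in place of -0.221.

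At 1 day edgeR gave 190 genes higher and 236 lower with an unadjusted p under 0.05, against 752 in all that chance alone would give on average. DESeq2 and limma-voom also called 0 genes, with 452 and 397 at that unadjusted threshold. The gene with the smallest p was CXCL10, a chemokine induced by interferon (ENSSSCG00000032474, chromosome 8, 71690758 to 71696162). It had 1.45 ± 0.586 CPM (SD, n = 6, range 0.66 to 2.08) after psilocybin and 3.77 ± 1.19 CPM (SD, n = 5, range 2.31 to 5.09) after saline, so that the groups did not overlap. Its log2 fold change of -1.41 ± 0.31 (SE) did not pass over all genes (adjusted p = 0.997), and its span overlaps that of ART3 on the other strand. Groups without overlap were found for 19 genes at 1 day, and exchanging the labels within batches gave 35.1 on average. Next came NMB, which encodes the bombesin-like peptide neuromedin B (chromosome 7, 52883128 to 52886644), with 4.25 ± 0.732 CPM after psilocybin and 7.34 ± 1.78 CPM after saline (log2 fold change -0.81 ± 0.18). At 1 week NMB had 4.99 ± 1.21 CPM after psilocybin and 4.79 ± 1.06 CPM after saline, so the saline 1 day group was the one that stood apart. The inflammatory cytokine gene IL18 (-0.59 ± 0.17), the growth factor gene IGF1 (-0.94 ± 0.30), the carboxypeptidase inhibitor gene LXN (-0.60 ± 0.18), the transcription factor gene PAX9 (-0.86 ± 0.27) and LRRC36 (-0.98 ± 0.28) had negative log2 fold changes that did not pass. ASS1, an enzyme of arginine synthesis (0.50 ± 0.14), the autophagy gene ATG2A (0.30 ± 0.09) and the glycosyltransferase gene GALNT16 (0.29 ± 0.09) had positive ones. All 10 genes had adjusted p values from 0.997 to 1 with edgeR. Over all genes at 1 day the smallest adjusted p was 0.0804 with DESeq2 and 0.084 with edgeR on the compared groups alone.

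Of the 12 genes chosen in advance, 11 were tested. HTR1A had no match among the symbols and was not analysed here. HTR2A, the 5-HT2A receptor gene (ENSSSCG00000037452, chromosome 11, 20555709 to 20620561), had 14.9 ± 4.74 CPM after psilocybin and 17.6 ± 4.29 CPM after saline at 1 day (log2 fold change -0.23, 95% confidence interval -0.66 to 0.20), and its fold change was -0.44 without psilocybin animal 4 and -0.11 without saline animal 4. The 5-HT2C receptor gene HTR2C had -0.10 (-0.34 to 0.15). BDNF, a neurotrophin, had 0.01 (-0.36 to 0.38), and its receptor NTRK2 had 0.11 (-0.13 to 0.34). SV2A, a synaptic vesicle protein gene, had 402 ± 68.4 CPM after psilocybin and 399 ± 96.1 CPM after saline (log2 fold change 0.03, -0.24 to 0.29). Among the activity-induced genes, FOS had 0.07 (-0.54 to 0.68), ARC 0.13 (-0.68 to 0.94), EGR1 -0.06 (-0.52 to 0.40), NR4A1 0.06 (-0.50 to 0.63) and DUSP1 0.06 (-0.33 to 0.45). The glucocorticoid-induced gene FKBP5 had 0.02 (-0.27 to 0.31). With edgeR 0 of the 11 passed over all genes, 0 passed when adjusted over the list alone (smallest adjusted p = 0.96), and 0 had an unadjusted p under 0.05. SV2A shares part of its span with BOLA1, and EGR1 with ETF1.

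**Figure D1:**
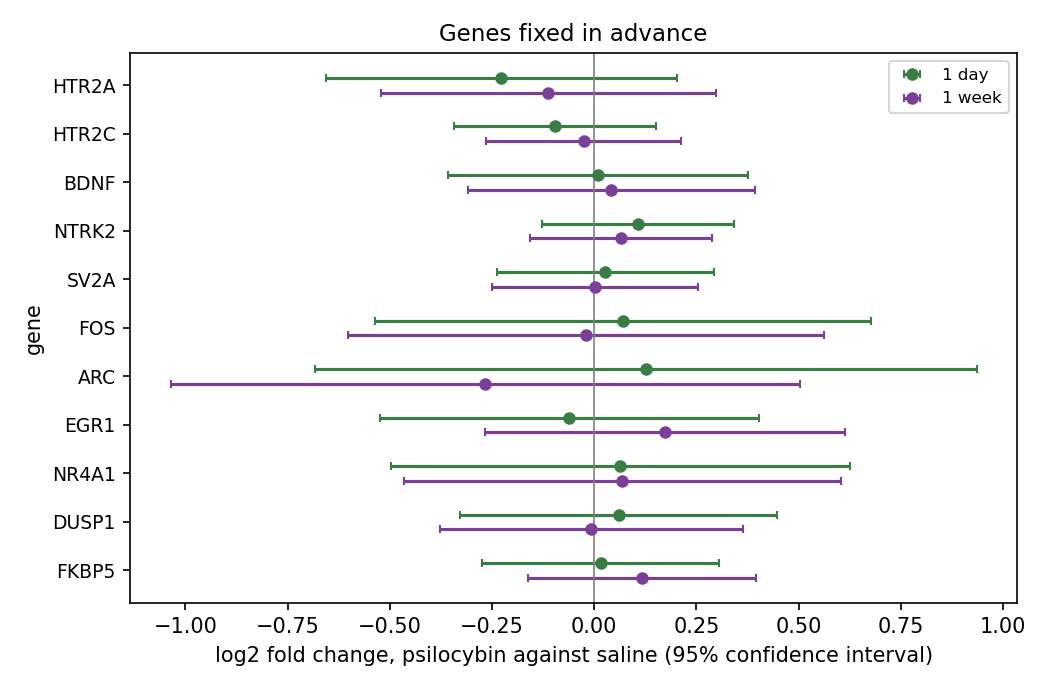
Log2 fold change of psilocybin against saline (horizontal axis) for 11 genes fixed in advance (vertical axis), at 1 day and at 1 week. Points are edgeR estimates and bars are 95% confidence intervals, and every interval includes 0, such as -0.66 to 0.20 for HTR2A at 1 day.

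Of 31 gene lists tested at 1 day, 10 passed camera, 4 higher and 6 lower. Ranges given beside camera's adjusted p at 1 day are over 22 alternatives that change the libraries or the model. The interferon response list had the smallest adjusted p (2.03e-10, range 4.72e-17 to 0.000763). The adjusted p was 0.593 with an estimated correlation, and the list score difference of -0.41 in batch 1 and -0.22 in batch 2 gave an exact permutation p of 0.11. Besides CXCL10, the members with the smallest p were the antiviral genes HERC5 (log2 fold change -0.34), GBP1 (-0.46) and IFIT1 (-0.48). Over all genes 0 members passed, and 1 (CXCL10) did when adjusted over the list alone. Antigen presentation genes were lower in 11 of 13 (median -0.17, adjusted p = 0.00952, and adjusted p = 0.586 with an estimated correlation), with SLA-DMA, a class II loading gene, at -0.44, the class II regulator CIITA at -0.16, the immunoproteasome gene PSMB10 at -0.22 and the cathepsin gene CTSS at -0.19. SLA-DMA had -0.18 without saline animal 2, CIITA -0.098 and PSMB10 -0.077 without saline animal 5, and CTSS -0.117 without psilocybin animal 4. That call was lost without psilocybin animal 4 (adjusted p = 0.0877), without saline animal 2 (0.101) and in batch 2 alone (range 0.00141 to 0.151). Microglia markers were lower in 14 of 18 (median -0.13, adjusted p = 0.0404, and adjusted p = 0.808 with an estimated correlation). LY86 had -0.75, AIF1 -0.26 and SPI1 -0.17, and CD68, a lysosomal marker of macrophages, had 0.30. Without saline animal 5 AIF1 had -0.05 and SPI1 -0.051. The call was lost on leaving out any 1 of psilocybin animals 3 and 4 and saline animals 1, 2, 4 and 5 (adjusted p 0.0641 to 0.894), and in 5 other alternatives, batch 1 alone among them (range 0.00144 to 0.894).

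The respiratory chain list gave an adjusted p of 2.36e-10, and adjusted p = 0.792 with an estimated correlation. Its members NDUFB5 (-0.42), NDUFV2 (-0.28) and NDUFB1 (-0.56) encode parts of complex I, and COX7B (-0.48) part of complex IV. The score difference was -0.05 in batch 1 and -0.23 in batch 2 (exact permutation p = 0.44). The ribosomal protein list gave an adjusted p of 1.06e-05, and adjusted p = 0.808 with an estimated correlation, with RPS3A at -0.36, RPL14 at -0.37, RPL38 at -0.40 and RPS15A at -0.37. Its score difference was 0.03 in batch 1 and -0.27 in batch 2, so it did not hold within both batches (exact permutation p = 0.79). Saline animal 5 had the highest score of both lists among the 1 day animals (0.56 and 0.87). Without it the respiratory chain call was lost (mean log2 fold change 0.00 in place of -0.19, adjusted p = 0.803, range 4.08e-14 to 0.803; NDUFB5 -0.073, NDUFV2 -0.101, NDUFB1 -0.06 and COX7B -0.054), and the ribosomal list passed in the opposite direction (mean 0.10 in place of -0.22, adjusted p = 0.0029, range 5.51e-11 to 0.788). Both calls were also lost in batch 1 alone, and the ribosomal one with 1 surrogate variable. Without the 3 libraries standing apart, an alternative added after the data were seen, 10 lists passed, of which the respiratory chain, perineuronal net, microglia and postsynaptic lists were not part and the ribosomal list was higher (adjusted p = 4.75e-06).

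The astrocyte list gave an adjusted p of 0.00016, and adjusted p = 0.593 with an estimated correlation. Its members included CBS (0.28), a cysteine synthesis enzyme, the transcription factor gene SOX9 (0.19), ALDH1L1 (0.19) and ACSBG1 (0.14). Saline animal 1 had the lowest astrocyte score of its group (-0.58), and the call was lost without it (adjusted p = 0.314, range 6e-08 to 0.314). Perineuronal net and extracellular matrix genes were higher in 17 of 22 (median 0.11, adjusted p = 0.00829, and adjusted p = 0.680 with an estimated correlation). The chondroitin sulphate proteoglycan genes BCAN (0.25), NCAN (0.19) and VCAN (0.26) and the thrombospondin gene THBS1 (0.32) were its members with the smallest p. This call was lost without saline animal 5 (adjusted p = 0.291), in batch 1 alone, without a batch term and with 1 surrogate variable (range 0.00141 to 0.3). Oligodendrocyte precursor markers were higher in 9 of 11 (median 0.13, adjusted p = 0.0209, and adjusted p = 0.506 with an estimated correlation), with MEGF11 at 0.27, GPR17 at 0.23 and the growth factor receptor gene PDGFRA at 0.46. VCAN belongs to this list as well. It was lost without psilocybin animal 2 or saline animal 1 or 4 (adjusted p 0.0574 to 0.139), in batch 1 alone and without a batch term (range 0.0114 to 0.139).

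Neuropeptide genes were lower in 12 of 16 at 1 day (median -0.07, adjusted p = 0.0351, and adjusted p = 0.791 with an estimated correlation). After NMB, which passed when adjusted over the list alone, came TAC1, the precursor of substance P (-0.45), the dynorphin precursor gene PDYN (0.48) and CARTPT (-0.16). PDYN had 0.249 without psilocybin animal 3 and 0.954 without saline animal 2, and CARTPT -0.271 without psilocybin animal 6 and -0.059 without saline animal 5. Leaving out any 1 of psilocybin animals 2, 3 and 5 and saline animals 1, 3 and 4 ended the call (adjusted p 0.0613 to 0.343), as did 5 other alternatives, each batch alone among them (range 0.0041 to 0.343). Postsynaptic glutamate receptor and scaffold genes were higher in 26 of 33 (median 0.07, adjusted p = 0.0464, and adjusted p = 0.808 with an estimated correlation). The adhesion gene NLGN3 had 0.18, the kainate receptor gene GRIK3 0.33, and the scaffold genes DLG1 and HOMER2 -0.13 and -0.14. The call was lost on leaving out any 1 of psilocybin animals 2, 3, 4 and 6 and saline animals 1, 2 and 5 (adjusted p 0.0663 to 0.81), and in 6 other alternatives, each batch alone among them (range 0.00251 to 0.81). Immediate early genes did not pass (21 of 31 higher, median 0.06, adjusted p = 0.583), nor did genes of the serotonin system (4 of 9 higher, median -0.10, adjusted p = 0.580) or of neurotrophin, mTOR and plasticity signalling (15 of 26 higher, median 0.03, adjusted p = 0.583). The blood cell list and the choroid plexus and ependymal list had too few expressed members and were not tested. With an estimated correlation, with fry and by exact permutation of the list scores, 0 of the 31 lists passed at 1 day (smallest adjusted p 0.506, 0.805 and 0.897).

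**Figure D2:**
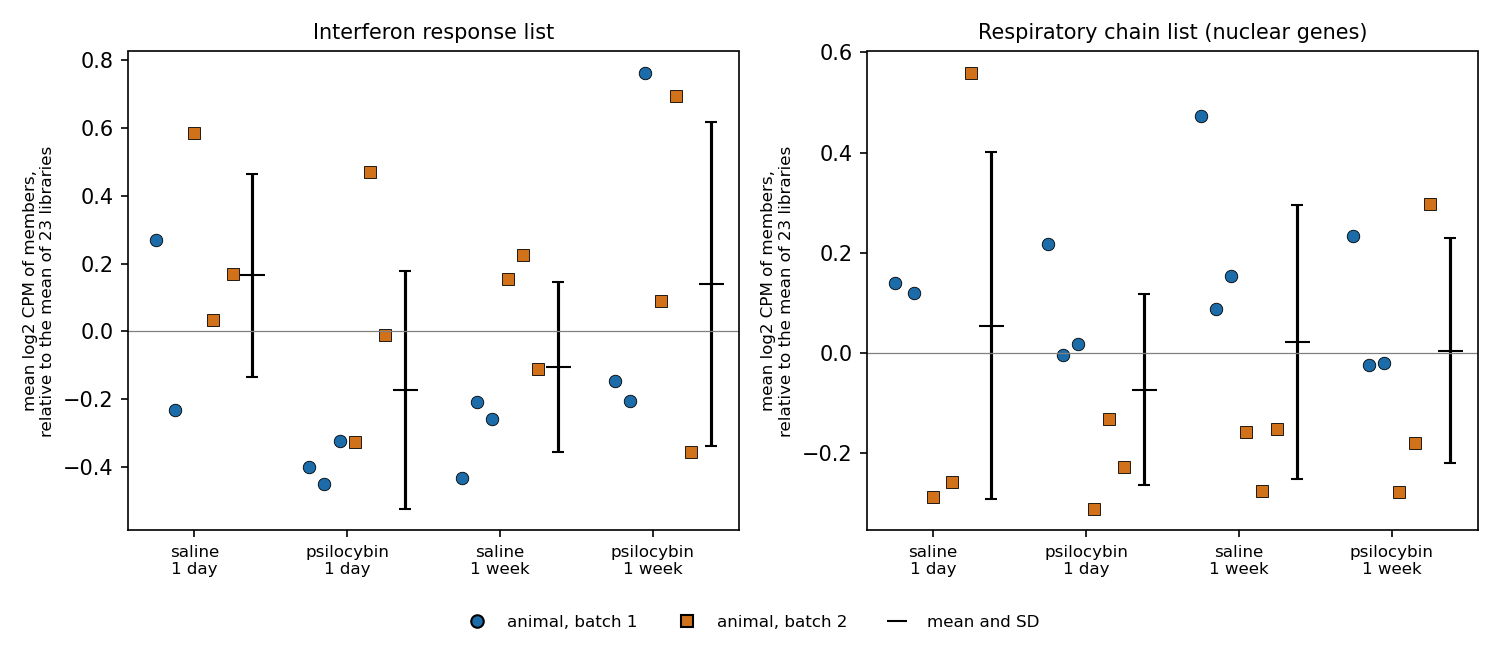
Mean log2 score of the interferon response list and the respiratory chain list (vertical axes, relative to the mean over 23 libraries) for each animal, by treatment and time (horizontal axis), with colour for batch and bars for the group mean and SD. The interferon score was -0.17 ± 0.35 and 0.17 ± 0.30 at 1 day, and 0.14 ± 0.48 and -0.11 ± 0.25 at 1 week, after psilocybin and saline respectively, and the animals of the groups overlap.

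The second comparison asked whether expression differs 1 week after psilocybin. Interferon response genes were higher in 34 of 37 (median log2 fold change 0.28), the opposite direction from 1 day. All 13 mitochondrially encoded genes were lower (median -0.12). Both lists passed camera with a preset correlation but not with an estimated one (adjusted p = 0.878 for each), and both calls were lost in batch 2 alone. No single gene passed: 0 of 15049 passed with edgeR, 0 with DESeq2 and 0 with limma-voom, and 300 had an unadjusted p under 0.05 with edgeR and 318 with DESeq2. With edgeR 181 of those 300 were higher and 119 lower.

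The gene with the smallest p at 1 week was CENPF, which encodes a centromere protein of dividing cells (ENSSSCG00000015581, chromosome 9, 128949182 to 129008793). It had 2.58 ± 0.464 CPM after psilocybin and 1.58 ± 0.407 CPM after saline (SD, n = 6 each), with a log2 fold change of 0.72 ± 0.20 that did not pass (adjusted p = 1). MET, the receptor of hepatocyte growth factor, had 4.31 ± 0.516 and 2.67 ± 0.732 CPM (0.68 ± 0.19). TRIM14, an adaptor of antiviral signalling (0.37 ± 0.11), TMEM132D (0.37 ± 0.11), BMP3 (0.78 ± 0.26), the condensin subunit gene NCAPG2 (0.44 ± 0.15) and the replication factor gene GINS3 (0.74 ± 0.25) had positive log2 fold changes. The interleukin 1 coreceptor gene IL1RAP (-0.26 ± 0.08), the mannosyltransferase gene ALG2 (-0.31 ± 0.11) and GATAD1 (-0.20 ± 0.07) had negative ones. Each of these had an adjusted p of 1.

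At 1 week HTR2A had 17.5 ± 3.98 CPM after psilocybin and 18.9 ± 3.93 CPM after saline (log2 fold change -0.11, 95% confidence interval -0.52 to 0.30), and its fold change was -0.224 without saline animal 6 and -0.005 without psilocybin animal 4. HTR2C had -0.03 (-0.26 to 0.21), BDNF 0.04 (-0.31 to 0.39), NTRK2 0.07 (-0.16 to 0.29) and SV2A 0.00 (-0.25 to 0.25). FOS had -0.02 (-0.60 to 0.56), ARC -0.27 (-1.04 to 0.50), EGR1 0.17 (-0.27 to 0.61), NR4A1 0.07 (-0.47 to 0.60), DUSP1 -0.01 (-0.38 to 0.36) and FKBP5 0.12 (-0.16 to 0.40). As at 1 day, 0 of the 11 passed with edgeR over all genes, 0 when adjusted over the list alone (smallest adjusted p = 0.995) and 0 at an unadjusted p under 0.05.

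Of 31 lists at 1 week, 2 passed camera. The interferon response list had an adjusted p of 2.95e-10, and adjusted p = 0.878 with an estimated correlation. Its members with the smallest p were GBP1 (0.41), IFIT1 (0.46) and the antiviral genes RSAD2 (1.23 ± 0.63) and BST2 (0.54), and 0 of 37 passed alone. Without psilocybin animal 3 RSAD2 had 0.39, IFIT1 0.17 and GBP1 0.241. The list score was higher by 0.44 in batch 1 and by 0.05 in batch 2 (exact permutation p = 0.34). The call was lost in batch 2 alone (adjusted p = 0.552) and without psilocybin animal 3 (0.0695), with a range of 1.61e-15 to 0.552 over 23 alternatives. The mitochondrially encoded list had an adjusted p of 0.0451, and adjusted p = 0.878 with an estimated correlation. The complex I genes ND1 (-0.17), ND6 (-0.15) and ND2 (-0.12) and the cytochrome b gene CYTB (-0.17) led it. Leaving out any 1 of psilocybin animals 2 and 3 and saline animals 1, 4 and 6 ended that call (adjusted p 0.0582 to 0.22), as did no filter, batch 2 alone and 1 surrogate variable (range 1.44e-05 to 0.91). Without psilocybin animal 6 camera called 11 lists, and 10 without the 3 libraries standing apart. Immediate early genes (18 of 31 higher, median 0.02, adjusted p = 0.585) and serotonin system genes (4 of 9 higher, median -0.03, adjusted p = 0.892) did not pass. Circadian clock genes had the smallest exact permutation p of the list scores (p = 0.02, 0.62 after adjustment over 31 lists).

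The difference between the effects at 1 week and at 1 day was tested directly. Interferon response genes had the more positive effect at 1 week in 35 of 37 (median difference 0.54), and antigen presentation genes in 12 of 13 (median 0.27). Both lists passed camera with a preset correlation but not with an estimated one (adjusted p = 0.176 for each). No single gene passed with edgeR (0, with 304 at an unadjusted p under 0.05), DESeq2 (0, with 307) or limma-voom (0, with 282). Camera called 7 lists, 6 with a more positive effect at 1 week and 1 less. Ranges here are over 33 alternatives. The interferon list had an adjusted p of 1.00e-23 (range 4.87e-35 to 0.00692), and adjusted p = 0.176 with an estimated correlation. Its score difference was 0.56, with 0.84 in batch 1 and 0.27 in batch 2 (exact permutation p = 0.0541, not under 0.839 after adjustment over 31 lists). The antigen presentation list had an adjusted p of 0.00061, and adjusted p = 0.176 with an estimated correlation (exact permutation p = 0.0486, 0.839 after adjustment over 31 lists), and its call was lost in batch 2 alone (range 1.26e-05 to 0.267). Microglia markers followed in 16 of 18 (median 0.18, adjusted p = 0.0135, and adjusted p = 0.978 with an estimated correlation) and complement genes in 10 of 14 (median 0.16, adjusted p = 0.0469, and adjusted p = 0.978 with an estimated correlation).

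Respiratory chain genes had the more positive effect at 1 week in 48 of 56 (median 0.19, adjusted p = 5.63e-05) and ribosomal protein genes in 42 of 45 (median 0.22, adjusted p = 0.00616). Both had an adjusted p of 0.978 with an estimated correlation, and both went the other way in batch 1 (score differences of -0.12 and -0.31, against 0.37 and 0.51 in batch 2). Without saline 1 day animal 5 the ribosomal list passed in the opposite direction (mean -0.10, adjusted p = 0.00556) and the respiratory chain call was lost (0.754). In batch 1 alone both passed in the opposite direction (adjusted p = 1.15e-12 and 0.000852), and without the 3 libraries standing apart the ribosomal list did (9.82e-06) and the respiratory chain call was lost (0.188). Over all alternatives the ranges were 1.15e-12 to 0.727 and 2.41e-11 to 0.754. The latter was also lost without psilocybin 1 week animal 6 (0.204). The ribosomal call was also lost without a batch term (0.0614) and without psilocybin 1 day animal 3 or 4, psilocybin 1 week animal 1 or 6, or saline 1 week animal 2 or 4 (adjusted p 0.0582 to 0.727). Astrocyte markers had the less positive effect in 11 of 15 (median -0.08, adjusted p = 0.0135, and adjusted p = 0.978 with an estimated correlation). Their call was lost without 7 animals in turn, most of all without saline 1 day animal 1 (adjusted p = 0.785), and also without psilocybin 1 day animals 2 and 5, psilocybin 1 week animal 1, saline 1 day animal 4 or saline 1 week animals 1 and 2 (0.0553 to 0.235), and in batch 2 alone (range 0.000321 to 0.988). The microglia call was lost without psilocybin 1 day animal 4, psilocybin 1 week animals 1, 3 and 5, saline 1 day animals 2 and 4 or saline 1 week animal 2 (0.0625 to 0.501), with no filter, without a batch term and in each batch alone (range 3.67e-05 to 0.501). The complement call was lost on leaving out any 1 of 11 animals, namely psilocybin 1 day animals 2 and 4, psilocybin 1 week animals 1, 3, 4 and 5, saline 1 day animals 2 and 4 and saline 1 week animals 2, 3 and 4 (0.0522 to 0.486), with no filter, without a batch term, with 1 surrogate variable and in each batch alone (range 1.26e-05 to 0.506). Across the 15049 genes, the effects at the 2 times had a Pearson r of 0.118 and a Spearman rho of 0.121. Genes are not independent replicates, and leaving out each animal in turn gave r from 0.004 to 0.187 (jackknife SE 0.235).

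**Figure D3:**
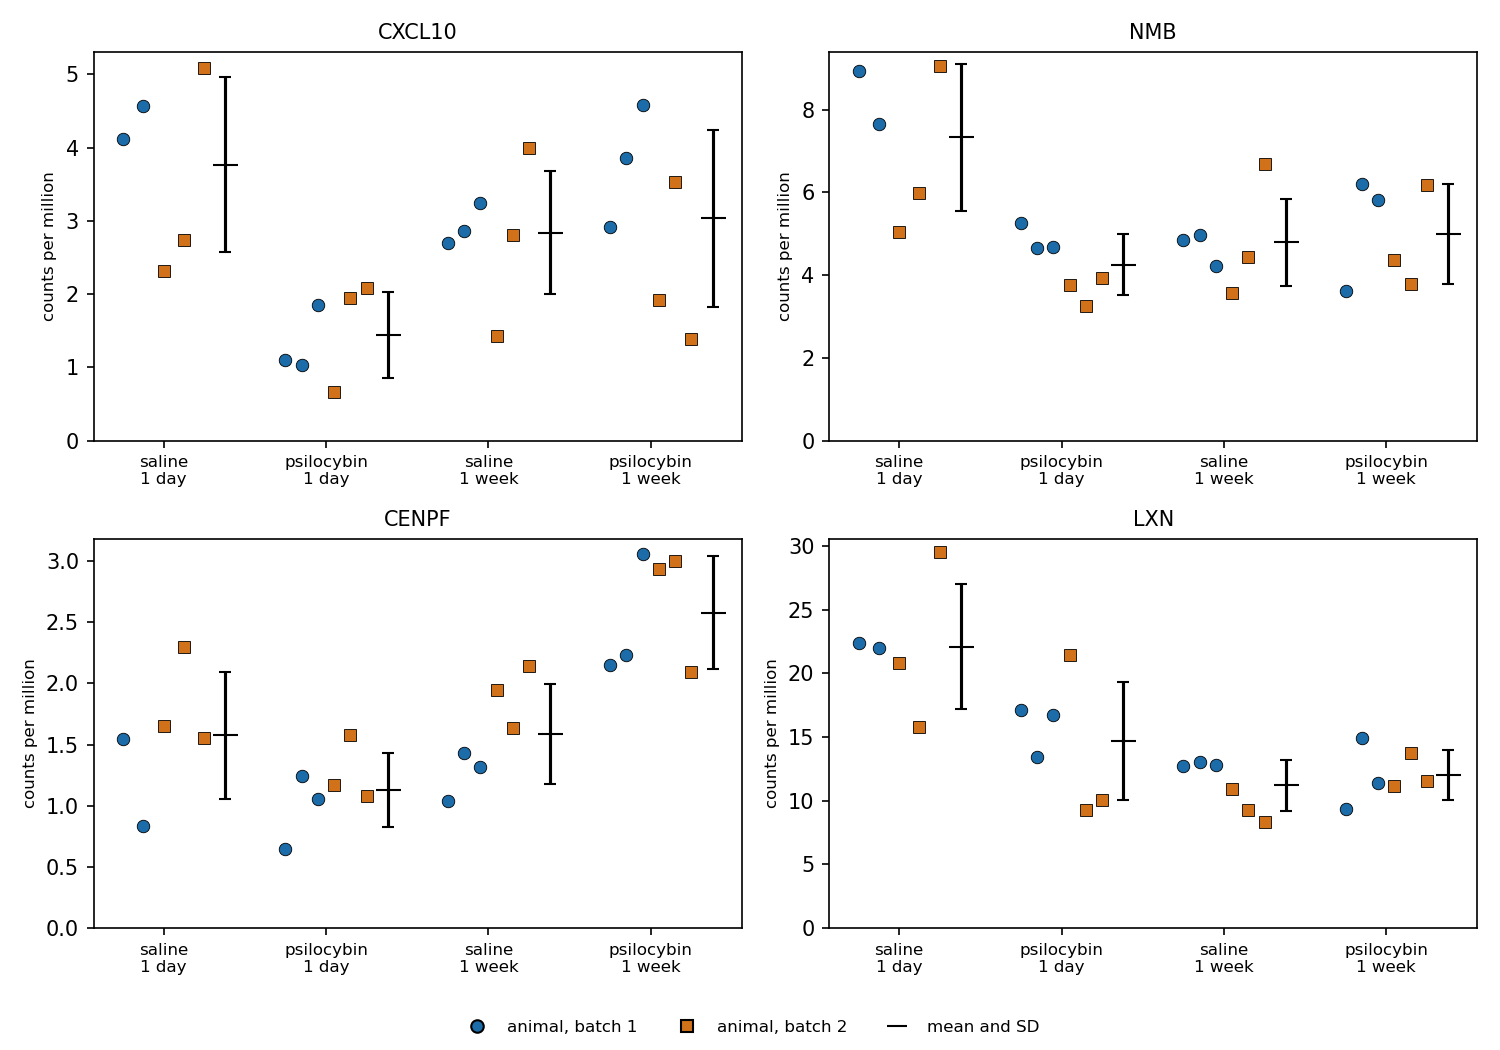
CPM (vertical axes) of CXCL10, NMB, CENPF and LXN in each animal, by treatment and time (horizontal axis), with colour for batch and bars for the group mean and SD. CXCL10 lay between 0.66 and 2.08 CPM 1 day after psilocybin and between 2.31 and 5.09 CPM 1 day after saline, and none of these genes passed with edgeR.

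Averaged over both times, respiratory chain genes were lower after psilocybin in 53 of 56 (median -0.11, adjusted p = 1.13e-06, and adjusted p = 0.912 with an estimated correlation) and ribosomal protein genes in 44 of 45 (median -0.12, adjusted p = 0.000955, and adjusted p = 0.912 with an estimated correlation). Neuropeptide genes were lower in 13 of 16 (median -0.07, adjusted p = 0.00612). Perineuronal net genes (18 of 22, median 0.07, adjusted p = 0.0011), astrocyte markers (12 of 15, median 0.09, adjusted p = 0.00511) and postsynaptic genes (27 of 33, median 0.04, adjusted p = 0.00802) were higher. With an estimated correlation the adjusted p was 0.733 for neuropeptide, perineuronal net and astrocyte genes and 0.747 for postsynaptic genes. No single gene passed on average: edgeR, DESeq2 and limma-voom called 0, with 457 at an unadjusted p under 0.05 in edgeR and 479 in DESeq2, whose smallest adjusted p was 0.052. Of the 11 genes fixed in advance 0 passed, also when adjusted over the list alone, in the average, the difference or the time comparisons. Without saline 1 day animal 5 the respiratory chain, ribosomal and postsynaptic calls were lost (adjusted p = 0.67, 0.216 and 0.465), and the mean of the ribosomal genes was 0.05. The ribosomal call was also lost without psilocybin 1 day animal 4 (0.0555) or saline 1 week animal 1 (0.377), the astrocyte call without saline 1 day animal 1 (0.376) or saline 1 week animal 6 (0.0697), and the neuropeptide call without psilocybin 1 day animal 2 (0.0508). The postsynaptic call was lost as well without psilocybin 1 day animal 4, psilocybin 1 week animal 2 or saline 1 week animal 1 or 6 (0.0519 to 0.0714). Batch 2 alone ended the respiratory chain, ribosomal, neuropeptide and postsynaptic calls, batch 1 alone the astrocyte call, and 1 surrogate variable all but the astrocyte call, with the ribosomal list passing as higher (adjusted p = 3.18e-06). Without the 3 libraries standing apart the respiratory chain, ribosomal and postsynaptic calls were lost (0.073, 0.112 and 0.597), and without a batch term the postsynaptic call (0.11). The highest adjusted p over 33 alternatives was 0.67 for respiratory chain, 0.397 for ribosomal, 0.27 for neuropeptide, 0.228 for perineuronal net, 0.376 for astrocyte and 0.998 for postsynaptic genes.

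The change from 1 day to 1 week was then compared within each treatment. In saline animals LXN had 22.1 ± 4.90 CPM at 1 day (n = 5) and 11.2 ± 2.02 CPM at 1 week (n = 6), a log2 fold change of -1.0 ± 0.19 that did not pass with edgeR (adjusted p = 0.241). DESeq2 called it as its only gene (-1.01, adjusted p = 0.00345), and over the alternatives its adjusted p ran from 0.00345 to 1. In psilocybin animals LXN had 14.7 ± 4.64 and 12.02 ± 1.99 CPM. CENPF had 1.13 ± 0.302 CPM 1 day and 2.58 ± 0.464 CPM 1 week after psilocybin (log2 fold change 1.21 ± 0.21, adjusted p = 0.0917 with edgeR), and 1.58 ± 0.52 and 1.58 ± 0.407 CPM after saline. DESeq2 called CENPF alone (1.20, adjusted p = 0.0192), and edgeR called it once psilocybin 1 week animal 6 was left out (1.3, adjusted p = 0.0333), with adjusted p from 0.0192 to 1 over the alternatives. Both genes were singled out in these comparisons after their values were seen, and LXN shares part of its span with GFM1. With edgeR 0 genes passed in saline (303 at an unadjusted p under 0.05) and 0 in psilocybin animals (479), and with limma-voom 0 and 0 (298 and 453).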

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

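The permutation tests of list scores, the comparison of the batches, the omission of saline 1 day animal 5 and the comparison of small p counts between splits were chosen only after the results they bear on were seen. The other tests of this part were set beforehand.

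Single animals stood apart from their group by Dixon's ratio of gap to range in 20 cases, where chance alone picks about 1 in 20 groups. Those are 2 of 8 groups of library measures, 12 of 124 groups of list scores (6.2 by chance) and 6 of 174 groups of gene levels (8.7 by chance). Psilocybin 1 day animal 4 had 18654626 counts, where the other 5 had 9975409 to 12591327, and the lowest complement score of its group (-0.56). Psilocybin 1 week animal 1 had the highest share of mitochondrially encoded counts (15.64%, others 11 to 12.18%) and the highest score of the mitochondrially encoded list (0.358). It also had the lowest scores of Gq and G-protein signalling genes (-0.192) and of astrocyte markers (-0.13). Psilocybin 1 week animal 6, 1 of the 3 libraries standing apart on the first principal component, had the lowest scores of its group for endothelial markers (-0.456), mural and fibroblast markers (-0.452), lymphocyte markers (-0.397), inflammatory cytokines and NF-kB targets (-0.227) and glucocorticoid response genes (-0.179). Saline 1 day animal 1 had the lowest astrocyte score (-0.577, others -0.117 to 0.062). Psilocybin 1 day animal 1 had the highest heat shock and chaperone score (0.118), and saline 1 day animal 4 the highest hypoxia score (0.096). On the log2 CPM scale, ATG2A was lowest in saline 1 day animal 5 (5.501), PAX9 (0.536) and HERC5 (4.164) in saline 1 day animal 4, NTRK2 in saline 1 week animal 3 (9.102) and ND6 in saline 1 week animal 5 (10.746). SLA-DMA was highest in saline 1 day animal 2 (2.498, others 1.311 to 1.539), whose omission ends the call of the antigen presentation list at 1 day.

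The psilocybin effect differed between the times in camera's preset test for 7 lists. The adjusted p was 1.00e-23 for interferon response, 0.00061 for antigen presentation, 5.63e-05 for respiratory chain, 0.00616 for ribosomal protein, 0.0135 for astrocyte, 0.0135 for microglia and 0.0469 for complement genes. With an estimated correlation 0 of the 7 passed.

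Other splits of the animals show which counts chance can be excluded for. Treatment labels were exchanged within time and batch, and time labels within treatment and batch, in 100 splits with the real one included. The 0 genes called in each comparison leave nothing for the splits to test, since every split gives at least 0. The highest count in another split was 1 gene at 1 day, 3 at 1 week, 2 for the difference, 2 for the average and 1 for time in saline. For time in psilocybin animals 4 of the 99 other splits called any gene and 1 of these called 819. Such a split may point to a structure of the samples, and none was tested for. For the lists chance is not excluded. At 1 day 50 of 100 splits gave at least the real 10 lists (highest other 18), at 1 week 99 gave at least 2 (highest other 14), for the difference 66 gave at least 7 (highest other 16), and for the average 75 gave at least 6 (highest other 16). Camera called the interferon list in 59 of the 99 other splits at 1 day, in 75 at 1 week and in 63 for the difference.

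The interferon list was lower at 1 day and higher at 1 week after psilocybin, and its score changed between the times by 0.56. Variation between animals that the whole list shares is not excluded, as the exact permutation of the list score missed the threshold (p = 0.05415), which does not speak for it either. That p is not adjusted, and the smallest exact permutation p after adjustment over the 31 lists was 0.839. A different share of microglia, lymphocytes or endothelial cells stays open. With those 3 marker scores as covariates the change was 0.48 ± 0.265 (SE) instead of 0.555 ± 0.28. The rule set beforehand could not have excluded such a share. Even the change without covariates, less its error, lay below the bound of that rule. The error of the drop between the 2 fits was not estimated. Dependence on 1 batch cannot be told apart from an effect in both, because the changes of 0.843 ± 0.4 in batch 1 and 0.272 ± 0.427 in batch 2 have a ratio of 0.322 ± 0.529 (SE), and an effect of psilocybin that turns between the times stays open beside all of these.

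Respiratory chain and ribosomal protein genes were lower at 1 day after psilocybin. The mean log2 fold change of the 101 members was -0.206. Random sets of other genes matched on exon length and expression had a mean of -0.042 (95% between -0.065 and -0.018). Of 10000 sets 0.01% were as low, the smallest share they can give. By the rule set beforehand this counts against transcript length as the whole cause. The sets draw scattered genes while the members move together, so their range is too narrow and the share cannot decide. Members had a median exon length of 1810, against 3899 in other genes. Over 14437 genes outside all lists, length had a Spearman rho of 0.137 with the fold change and -0.34 with the loading on the first principal component. A part of length stays open. Saline animal 5 may carry the pattern, since without it the means went from -0.194 to 0.002 and from -0.221 to 0.098, where leaving out any other animal gave -0.251 to -0.168 and -0.316 to -0.151. Variation between animals shared by the whole list also stays open, with an exact permutation p of 0.44 for the respiratory chain score, the smaller of both lists. An effect of psilocybin stays open too.

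Fewer genes had an unadjusted p under 0.05 than chance gives on average, 190 higher and 236 lower at 1 day and 300 in all at 1 week, against 752. Leaving out each animal in turn gave 306 to 673 in all at 1 day and 190 to 583 at 1 week, still below 752. Simulated libraries of the same depth with independent genes gave 700 and 708 among 14834 unchanged genes. This is 1.64 and 2.36 times the real counts, which are over 15049 genes. The simulated counts were drawn from the means and dispersions that edgeR had fitted. Small samples or low counts alone are therefore argued against only where that model holds, and the simulation cannot decide where it does not. Genes that vary together across animals could make the count swing between splits. In 76 of 100 splits at 1 day and 77 at 1 week the count was at least as large as the real one. Other splits gave from 192 to 1899 (median 724) and from 142 to 2554 genes (median 487). The real counts were thus not unusual among the splits. Whether 1 shared factor holds the counts down was not settled. With 1 surrogate variable they were 502 and 363, which is 1.18 and 1.21 times the real counts. The spread of these ratios was not measured. Leaving out each animal moved the counts without a surrogate variable by an SD of 0.3 and 0.48 of their size.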

How the results depend on the processing

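The omission of the 3 libraries standing apart (saline 1 day animal 5, saline 1 week animal 1 and psilocybin 1 week animal 6) and all alternatives for the batches and for the lists of the time comparisons were chosen only after the data were seen, and the other alternatives beforehand. Counts of changed genes were 0 with edgeR in all 6 comparisons and stayed 0 under the alternatives run, except that DESeq2 called 1 gene for time in saline animals (LXN) and 1 for time in psilocybin animals (CENPF), and that leaving out each animal gave 0 to 1 genes for time in psilocybin animals, with 1 (CENPF) without psilocybin 1 week animal 6. Of 2029 fold changes of named genes under the alternatives, 1935 kept their direction and 94, in 25 of 87 gene and comparison pairs, did not, and 0 passed the threshold. DESeq2 was not run for lists, and the alternative with the compared groups alone gives no separate value for the difference or the average, which use all groups. The correlation of effects across genes and the mitochondrially encoded shares moved by less than their spread. At these depths genes near 1 CPM, such as IGF1, CENPF and, 1 day after psilocybin, CXCL10, rest on few counts per library. Where no reason is given, the cause was not tested.

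Lists called by camera numbered 10 at 1 day, 2 at 1 week, 7 for the difference and 6 for the average. With an estimated correlation the counts were 0, 0, 0 and 0, and with fry 0, 0, 0 and 0, since these tests take in the correlation within each list, estimated at 0.724 for respiratory chain and 0.883 for ribosomal protein genes in the average comparison. With 1 surrogate variable 5 lists passed at 1 day and 2 for the average. In batch 1 alone 4 passed at 1 day and 7 at 1 week, and in batch 2 alone 4 at 1 week, with fewer animals in each. Without a batch term 5 passed at 1 day and 4 for the difference. With no filter 1 passed at 1 week, with the compared groups alone 6, and without the 3 libraries 10. Leaving out each animal gave 5 to 10 lists at 1 day (5 without saline animal 1), 0 to 11 at 1 week (0 without psilocybin animal 3 and 11 without psilocybin animal 6) and 3 to 9 for the difference (3 without psilocybin 1 week animal 1 and 3 without saline 1 week animal 2). For the lists differing between the times it gave 3 to 9 in saline animals, where 6 were called, and 3 to 13 in psilocybin animals, where 10 were called, and for the batches 10 to 11, where 10 were called.

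Fold changes of opposite sign to the main estimate were found as follows, on the log2 scale, mostly for genes with estimates near 0. With 1 surrogate variable they were FKBP5 at 1 day (-0.037) and DUSP1 (0.001), FOS (0.019) and SV2A (-0.047) at 1 week. SV2A at 1 week had -0.003 with DESeq2, -0.003 with RLE size factors, -0.003 with no filter and -0.005 without a batch term, where DUSP1 at 1 week had 0.004 and FKBP5 at 1 day -0.016. With limma-voom they were FKBP5 at 1 day (-0.004) and ARC (0.012), DUSP1 (0.018) and FOS (0.116) at 1 week, and with the compared groups alone FOS at 1 week (0.001). In batch 1 alone they were AIF1 (0.028), BDNF (-0.2), EGR1 (0.021), FOS (-0.036), HTR2C (0.065), PDYN (-0.057), RPL14 (0.006) and RPS15A (0) at 1 day, and DUSP1 (0.157) and FOS (0.173) at 1 week. In batch 2 alone they were ARC (-0.08) and FKBP5 (-0.086) at 1 day, and BDNF (-0.061), EGR1 (-0.014), FKBP5 (-0.029), HTR2C (0.006), NTRK2 (-0.045) and SV2A (-0.112) at 1 week. Without the 3 libraries they were BDNF (-0.105), NR4A1 (-0.007), RPL14 (0.033), RPL38 (0.029), RPS15A (0.061), RPS3A (0.003) and SV2A (-0.094) at 1 day, and BDNF (-0.001) and SV2A (-0.031) at 1 week.

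Leaving out each animal in turn at 1 day gave log2 fold changes from -0.143 to 0.381 for ARC, -0.102 to 0.185 for DUSP1, -0.212 to 0.023 for EGR1, -0.146 to 0.18 for FOS, -0.136 to 0.228 for NR4A1, -0.107 to 0.155 for BDNF, -0.061 to 0.077 for FKBP5, -0.165 to 0.045 for HTR2C and -0.094 to 0.109 for SV2A. The ribosomal protein genes ran from -0.488 to 0.033 for RPL14, -0.522 to 0.029 for RPL38, -0.509 to 0.061 for RPS15A and -0.478 to 0.003 for RPS3A, each highest without saline animal 5. At 1 week the values ran from -0.035 to 0.152 for BDNF, -0.046 to 0.033 for SV2A, -0.07 to 0.045 for HTR2C, -0.096 to 0.095 for DUSP1, -0.478 to 0.208 for ARC, -0.213 to 0.26 for FOS and -0.088 to 0.337 for NR4A1.

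Other named genes of which leaving out 1 animal moved the fold change by over 1.5 times kept their direction. At 1 day the values ran from 0.014 to 0.206 for NTRK2, 0.085 to 0.236 for NLGN3, -0.195 to -0.06 for HOMER2, 0.157 to 0.431 for GRIK3, 0.16 to 0.309 for VCAN, 0.213 to 0.401 for THBS1, 0.123 to 0.227 for SOX9, 0.065 to 0.202 for ACSBG1, 0.127 to 0.316 for GPR17 and 0.192 to 0.412 for CD68. NLGN3, THBS1 and GPR17 were lowest without saline animal 5, SOX9, VCAN and CD68 without psilocybin animal 5, ACSBG1 without saline animal 1, NTRK2 without saline animal 2 and GRIK3 without psilocybin animal 4, and HOMER2 was nearest 0 without saline animal 1. At 1 week they ran from 0.011 to 0.102 for NTRK2 and 0.043 to 0.218 for FKBP5, each lowest without psilocybin animal 3, and from 0.028 to 0.364 for EGR1, lowest without saline animal 3 and highest without saline animal 5.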

Other observations

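The test of cell-cycle genes and the splits of the batches were set before their results were seen. The list tests of the time comparisons and of the batches, their alternatives, the alternatives for the batch counts, the relations between list scores and the counts of genes without overlap were looked at only after the data had been seen.

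Batch was the strongest difference between the libraries: 4955 of 15049 genes differed with edgeR, 2428 higher and 2527 lower in batch 2. The neural adhesion gene NCAM2 had 18.4 ± 5.55 CPM in batch 1 (n = 11) and 43.0 ± 6.86 CPM in batch 2 (n = 12), a log2 fold change of 1.24 ± 0.14 (SE). FAM199X (0.88), DOK6 (1.26), the integrin gene ITGB8 (0.75) and DPP10, a subunit of potassium channels (0.95), were also higher in batch 2. CCDC136 (-0.39), the transcription factor gene NR2F1 (-0.51), the growth factor gene FGF18 (-1.03), OIP5 (-0.57) and PDLIM7 (-0.44) were lower. All 18 microglia markers were lower in batch 2 (median -0.44, adjusted p = 2.24e-06 with camera, 0.00156 with fry, and adjusted p = 0.394 with an estimated correlation), and so were 51 of 56 respiratory chain genes (median -0.26, adjusted p = 1.11e-06, and adjusted p = 0.657 with an estimated correlation). GABA receptor genes were higher in 14 of 15 (median 0.18, adjusted p = 0.00015, and adjusted p = 0.394 with an estimated correlation), and excitatory neuron markers in 12 of 16 (median 0.26, adjusted p = 0.00772, and adjusted p = 0.394 with an estimated correlation). Of 100 splits of the animals within groups only the real one gave as many genes as 4955 (highest other 982, and 3 of the others above 0), so chance is excluded for the gene count. Camera called 10 lists, fry 13 and camera with an estimated correlation 0. At least 10 lists were called by camera in 36 of the 100 splits (highest other 18), so chance is not excluded for camera's count of lists. Fry was not run in the splits, so its 13 lists were not set against them. With 1 surrogate variable the count was 130, with limma-voom 5051, with no filter 4384 and without the 3 libraries standing apart 5799. The balance of directions moved as well. Without psilocybin 1 week animal 1, 2290 genes were higher and 1560 lower, and without psilocybin 1 day animal 1, 2395 and 1675. The labels do not say whether batch stands for sequencing or for the animals. The submitters' animal numbers fall into separate ranges, with every number in batch 1 below every number in batch 2. Batch may therefore go with separate sets of animals, and the genes differing between batches cannot be assigned to sequencing or to the animals.

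From 1 day to 1 week, astrocyte markers were higher at 1 week in 14 of 15 in saline animals (median log2 fold change 0.18, adjusted p = 1.01e-09, and adjusted p = 0.276 with an estimated correlation), and interferon response genes were lower in 33 of 37 (median -0.22, adjusted p = 3.6e-09, and adjusted p = 0.780 with an estimated correlation). In psilocybin animals interferon response genes were higher at 1 week in 35 of 37 (median 0.33, adjusted p = 2.16e-12, and adjusted p = 0.492 with an estimated correlation), antigen presentation genes in 11 of 13 (median 0.27, adjusted p = 0.00025, and adjusted p = 0.196 with an estimated correlation) and microglia markers in 17 of 18 (median 0.19, adjusted p = 0.00042, and adjusted p = 0.716 with an estimated correlation). Without saline 1 day animal 1 the mean log2 fold change of the astrocyte list in saline animals was 0.104 in place of 0.194 (adjusted p = 0.00627), and the call was lost in batch 2 alone (0.018, adjusted p = 0.585). The interferon mean in saline animals was -0.157 in place of -0.249 without saline 1 day animal 3 (adjusted p = 0.00149). In psilocybin animals it was 0.168 in place of 0.372 without psilocybin 1 week animal 3 (adjusted p = 0.000495), and the call was lost in batch 2 alone (0.12, adjusted p = 0.112), as was that of antigen presentation (0.153, adjusted p = 0.11). The microglia call was lost without psilocybin 1 day animal 4 (0.091 in place of 0.186, adjusted p = 0.247), without psilocybin 1 week animal 5 (0.105, adjusted p = 0.0653) and in batch 1 alone (0.048, adjusted p = 0.619). In psilocybin animals camera also called complement, lymphocyte and respiratory chain genes as higher at 1 week. It called oligodendrocyte, excitatory neuron, cholesterol synthesis and presynaptic vesicle genes as lower. Their adjusted p ran from 0.00315 to 0.0368, and each call was lost on leaving out at least 1 animal. Camera called 6 lists in saline and 10 in psilocybin animals, and at least 6 lists in 79 and at least 10 in 32 of 100 splits, so chance is not excluded (highest other 14 and 16).

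Over the 23 libraries the scores of respiratory chain and ribosomal protein genes rose and fell together (Pearson r = 0.959, Spearman rho = 0.952, each permutation p = 1e-05, the smallest that 100000 permutations can give). Adjusted over 465 pairs of lists the p values were 0.000179 and 0.000221. The permutations exchanged libraries across groups and batches, so no permutation p given here for pairs of lists allows for differences between the batches. The r was 0.921 in batch 1 and 0.975 in batch 2, 0.964 within groups, and 0.929 without the 2 libraries farthest from the median. Scores of postsynaptic glutamate receptor genes went the other way from respiratory chain genes (r = -0.884, rho = -0.909, permutation p = 1e-05 and 0.000179 after adjustment for r, -0.909 in batch 1 and -0.875 in batch 2, -0.853 without the 2 farthest) and with GABA receptor genes (r = 0.934, rho = 0.942, 0.875 in batch 1 and 0.902 in batch 2, 0.914 without the 2 farthest).

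Psilocybin and saline groups did not overlap for 19 genes at 1 day, where exchanging the labels within batches gives 35.1 on average (140 of 200 arrangements gave at least 19), and for 7 at 1 week, where it gives 18.4 (336 of 400 gave at least 7). Saline animals of the 2 times did not overlap for 21 genes (38.9 on average in exchanged labels, median 28) and psilocybin animals for 10 (18.4 on average, median 12).

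CENPF, NCAPG2 and GINS3, which act in cell division, were among the 10 genes with the smallest p at 1 week, and a hypothesis is that cell-cycle expression may be raised 1 week after psilocybin. Of 51 other cell-cycle genes 34 were tested, and 18 were higher (median log2 fold change 0.04). Their mean score was higher by 0.073 after psilocybin, by 0.184 in batch 1 and by -0.038 in batch 2 (exact permutation p = 0.325). The rule set beforehand counted any p of 0.05 or more against the hypothesis, which was wrong, since with 6 animals a side a p that misses the threshold does not show that the scores did not differ, so the hypothesis was neither excluded nor borne out.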
